A study of Mus musculus with 8 samples.

How the data were processed

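RNA from mouse mammary tumours was measured on 8 two-colour Agilent expression arrays of design 014868. The tumours arose in virgin females carrying MMTV-NIC, a transgene that expresses activated Neu (ErbB2) and Cre recombinase from 1 transcript in mammary epithelium, and were taken 6 weeks after a tumour could be felt, per the labels. The 5 samples of 1 group were single tumours with both Stat3 alleles floxed, and the 3 samples of the other were pools of 5 tumours each with wild-type Stat3. Tumour RNA was labelled with Cy5 and a universal mouse reference RNA with Cy3 on every array, so the dyes were never swapped and a dye bias of a probe cancels between groups only where it is equal on all arrays. Per the labels' protocols, RNA was extracted from frozen tissue with a column kit and amplified and labelled by the amino allyl method.

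Per the file headers, the deposited spot intensities were made with Agilent Feature Extraction 9.5.3.1 under protocol GE2-v5_95_Feb07, and probe coordinates refer to mouse build mm7. The mean and background intensity values of each spot were deposited without normalization, and the scanner software's processed intensity values were background-subtracted and dye-normalized, per the file headers. The authors' deposited value table holds log2 values, and the submitters' processing notes name Agilent Feature Extraction and RMA with no further detail. Each of its columns followed the log2 ratio of tumour over reference on its own array (r from 0.981 to 0.990, slope from 0.950 to 1.14), which settled its direction and an approximate log2 scale. Its column medians were 0.01 for floxed tumour 1, 0.00442 for floxed tumour 2, 0.00677 for floxed tumour 3, 0.00215 for floxed tumour 4, 0.00287 for floxed tumour 5, 0.00469 for wild-type pool 1, 0.00314 for wild-type pool 2 and 0.0048 for wild-type pool 3. How these values were normalized and centred stays unknown, so the table was used as an alternative.

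Background was corrected with normexp (offset 50), ratios were normalized by loess within each array with control spots at weight 0, and spots with an outlier flag in either channel were left out, with limma 3.58.1 in R 4.3.3. Spots of the same probe were averaged, which concerned 245 of 41174 probes, each with 10 spots. A probe was kept where the tumour channel was well above background on at least 3 of the 8 arrays, which left 31314 probes. A gene was represented by its brightest kept probe, giving 21539 genes, of which 21455 had a value on every array. Gene symbols came from the accession for 22951 probes and from an identical current symbol for 6659, and the file's own name was kept for 11564. Among the 42 genes named by rule, 14 had several probes, and those of Wfdc3 disagreed in sign.

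The groups were compared with limma's linear model and moderated statistics, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 33 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 33 lists, and again with an estimated correlation and with fry. Groups, gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Stat3, the genes past the threshold without overlap of the groups (filled to 5 per direction by smallest p), the 3 leading members of the Stat3 target, acute phase, immediate early and C/EBP lists, and the 3 leading members of each list past the threshold. The exact permutation test of a single gene enumerated all 56 splits of the 8 samples into 5 and 3, so its smallest possible p is 0.0179.

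Where a probe was not well above background on any array of a group, a fold, where given, is a lower bound in the tumour channel and open to dye bias. It was computed against the higher, on each array, of the lowest signal well above background and the dim probe's own signal. For Dppa1 the probe's own signal was the higher on each floxed array, so its bound equals the fold between its tumour-channel means. The median tumour-channel signal per array lay between 642 and 891, against background medians of 47 to 58, and 71.7% to 77.3% of probes were well above background. The number of arrays limits the precision. The 5 floxed samples were single tumours and the 3 wild-type samples pools, and replicate numbers of floxed tumours are names only.

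The arrays lay on 3 slides, each holding both groups: floxed tumours 2 and 3 with wild-type pool 3, floxed tumour 1 with pool 2, and floxed tumours 4 and 5 with pool 1. Alternatives were other background corrections and normalizations, the tumour channel alone, other filters and probe rules, slide as a fixed or random block or taken singly, other variance models, the authors' table, and each sample left out. With slide as a random block and with trended robust variances, lists were tested with camera's preranked form, since camera itself does not take those fits.

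The model was tested on simulated data. For the comparison of floxed tumours with wild-type pools, 21455 genes were simulated with limma's moderated gene-wise spread and 200 were shifted. At the threshold, 29.2% of genes shifted by 2-fold, 93.3% of genes shifted by 4-fold and 99.2% of genes shifted by 16-fold were recovered, and 6.85%, 4.75% and 3.97% of calls were false. With 200 shifted genes the adjustment is more lenient than in the data, where 1 gene passed. The recovered shares are thus too high for this comparison. Genes were simulated as independent, so false calls from shared variation between samples are not covered. With every member of the acute phase list lowered by 0.5 on the log2 scale, camera at its preset correlation called it in 10 of 10 simulated sets. In the data the estimated correlation of this list was 0.306 and its median difference -0.27. The simulated sets thus do not show how often camera would call such a list in these data. Figures were drawn with matplotlib 3.10.9.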

Results

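Transcript levels were measured in 5 single MMTV-NIC mammary tumours with floxed Stat3 and in 3 pools of 5 tumours with wild-type Stat3, each against a common reference RNA. The comparison asks which transcripts differ when Stat3, a transcription factor activated by cytokine and growth factor receptors, is deleted in tumours driven by activated ErbB2. Correlations of log2 ratios between arrays ranged from 0.864 to 0.964. The limma and exact permutation p-values measure the spread between these samples. Camera at its preset correlation sets the genes of a list against other genes, and Fisher's exact test counts genes. Their p-values thus treat genes rather than samples as the units. A pool of 5 tumours averages over differences between animals that a single tumour keeps.

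The Stat3 transcript itself was lower in the floxed tumours. Its log2 ratio was -1.30 ± 0.14 (SD, n = 5) in floxed tumours and 0.75 ± 0.58 (SD, n = 3) in wild-type pools, a 4.13-fold difference. The log2 difference was -2.05 with a standard error of 0.24, and all 5 floxed tumours lay below all 3 pools. The exact permutation test gave p = 0.0179, the smallest this design allows, while limma's adjusted p over all genes was 0.109. With slide as a fixed block the difference was -2.04 (limma adjusted p = 0.378). Within the slides of wild-type pools 3, 2 and 1 the difference was -2.68, -2.18 and -1.29. The probe lies on chromosome 11 at 100997323 to 100997382 of build mm7, on the minus strand. A second Stat3 probe, from a cDNA clone at 100994187 to 100994246, differed by -0.60 (adjusted p over probes = 0.921) and its groups overlapped. Whether either probe lies in the deleted part of Stat3 is not given in the sources used here, so neither checks the labels by itself.

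**Figure D1:**
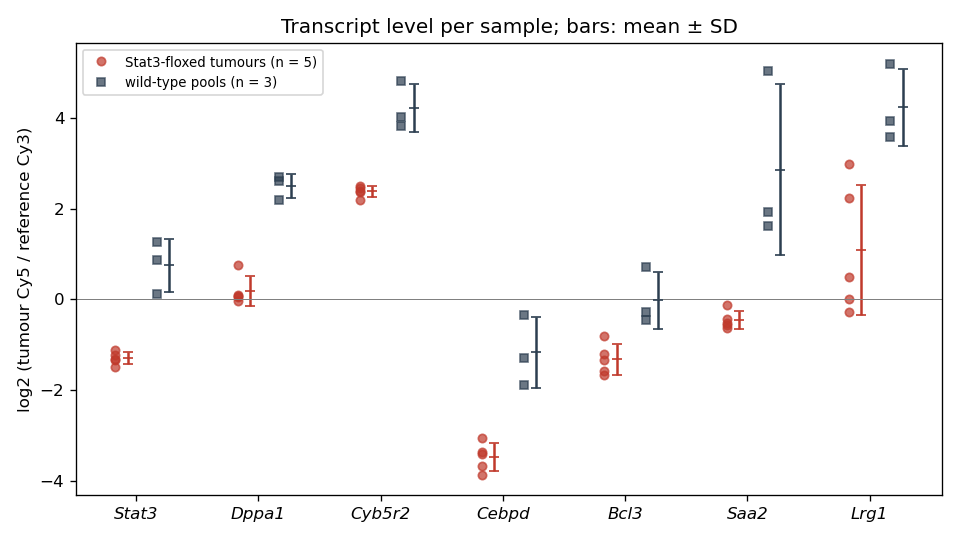
The log2 ratio of tumour (Cy5) to reference (Cy3) signal is plotted for 7 genes, with a circle for each of 5 Stat3-floxed tumours, a square for each of 3 wild-type pools, and bars for the mean ± SD. Stat3 averaged -1.30 in floxed tumours and 0.75 in pools, and Dppa1 was not well above background in any floxed tumour.

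Dppa1, named for its association with developmental pluripotency, was the only one of 21539 genes past the threshold. Its ratio fell (limma adjusted p = 0.0441), and it was well above background in all 3 wild-type pools and in none of the 5 floxed tumours. In the tumour channel its level was at least 4.61-fold lower, and with that channel alone it did not pass (limma adjusted p = 0.0549, range over alternatives 0.00469 to 0.378). The next genes by p were also lower but did not pass. They were Cyb5r2, a cytochrome b5 reductase (-1.84, adjusted p = 0.109), Ocm, the calcium-binding protein oncomodulin (not well above background in any floxed tumour, adjusted p = 0.109), and Clca3a1, of the calcium-activated chloride channel regulator family (-6.32, adjusted p = 0.114). Binding of the Clca3a1, Saa2 and Tgtp1 probes to transcripts of close paralogs was not tested. No gene passed in the higher direction. There the leading genes were Gpi1, a glycolytic enzyme, at 0.86 (adjusted p = 0.754), Usp6nl at 0.64 (0.872), and Mia3 at 0.72, the interferon-inducible guanylate-binding protein Gbp4 at 1.59 and Sp110 at 2.61 (each 0.942). The single call rests on the setting: Dppa1 did not pass with slide as a fixed block (limma adjusted p = 0.378) but did as a random block (0.0463). In the authors' deposited table no gene passed.

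At an unadjusted p under 0.05, 1070 genes differed (346 higher and 724 lower in floxed tumours), where 1077 are expected by chance. The count was 475 without wild-type pool 3, 1893 without pool 2 and 622 with median centring in place of loess. With the scanner software's processed signals the split was 421 higher and 562 lower. The groups did not overlap for 684 genes, or 3.18%, against 3.57% by chance. A second threshold, unadjusted p under 0.01 with at least a 1.5-fold difference, took 155 genes, 38 higher and 117 lower; it took 70 without wild-type pool 3, 440 without pool 2, 308 with slide as a fixed block and 101 with median centring.

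Genes described as Stat3 targets stood lower in floxed tumours as a list. Of 41 measured members 25 were lower and 16 higher, with a median of -0.13. The list includes Stat3, the floxed gene, and was not tested without it. Relative to the mean of the wild-type pools, the list median was -0.20 in wild-type pool 1. It was -0.13, 0.02, -0.33, -0.28 and -0.09 in floxed tumours 1 to 5, so the groups overlapped. Cebpd, a C/EBP transcription factor, differed by -2.30 (4.93-fold, adjusted p = 0.192), and Bcl3, an IκB family protein, by -1.30 (adjusted p = 0.942). None passed over all genes, while 6 passed adjusted over the list alone: Stat3 itself, Cebpd, Bcl3, Osmr, Lrg1 and Pik3r1. Acute phase genes had a median of -0.27, with 26 of 34 lower. Saa2 differed by -3.31 (adjusted p = 0.754), Lrg1 by -3.14 and the fibrinogen chain Fgg by -2.72 (each 0.942), and Saa2 and Lrg1 passed adjusted over the list alone. Milk protein and secretory genes had a median of -0.33, with Wap at -2.76, Lao1 at -1.66 and Wfdc3 at -1.98 (each 0.942), 24 of 34 lower. Camera's adjusted p was 0.0145 for Stat3 targets, 0.00473 for acute phase genes and 0.0226 for milk genes, and 0.745 for each with an estimated correlation. Wild-type pool 3 stood above pools 1 and 2 on all 3 lists. Its acute phase median was 0.41, against -0.36 and -0.20 for the other pools. In floxed tumours 1 to 5 the acute phase median was -0.06, -0.17, -0.43, -0.35 and -0.53, so these overlapped pools 1 and 2. The milk gene median was -0.13, -0.29, -0.43, -0.06 and -0.43 in floxed tumours 1 to 5. It was -0.37, -0.12 and 0.38 in pools 1 to 3, again with overlap of pools 1 and 2. Without pool 3 the differences were -1.47 for Fgg, -1.55 for Wap and -0.84 for Wfdc3. Another Wfdc3 probe gave 0.14, and the mean of its probes -0.92. Acute phase genes did not pass with the filter on all 8 arrays (adjusted p = 0.0570), nor milk genes in the authors' deposited table (0.0584).

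Interferon-stimulated genes stood higher in floxed tumours as a list, with a median of 0.51 and 40 of 49 members higher, but not in every tumour. Relative to the wild-type mean, the list median was 1.66 in floxed tumour 1, 0.89 in tumour 2 and 0.62 in tumour 4, and -0.28 in tumour 3 and -0.10 in tumour 5. Sp100 differed by 2.57 and Tgtp1 by 2.57 (each adjusted p = 0.942). Other Sp100 probes gave 1.20 and 0.74, and the mean of the Sp100 probes 1.51. The log2 ratio of Sp100 to the reference was 3.51, 0.37, 2.65, 1.96 and 2.95 in floxed tumours 1 to 5. It was thus high in tumours 3 and 5 and low in tumour 2, unlike the list median. T and natural killer cell markers had a median of 0.21, with 27 of 33 higher, among them Nkg7 at 0.69, Ncr1 at 1.00 (2.15 with processed signals) and Il2rb at 0.54. MHC class II and dendritic markers had a median of 0.23 (18 of 24 higher), with Ly75 at 1.01, Batf3 at 0.49 and Ciita at 0.36, the last being 0.23 without wild-type pool 1, 0.23 without pool 2 and 0.62 without pool 3. Camera's adjusted p was 9.71e-09 for the interferon list, 7.06e-05 for T and natural killer markers and 0.0253 for dendritic markers, and 0.745 for each with an estimated correlation.

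The other lists past camera's preset threshold were higher in floxed tumours. Of these, 3 no longer passed without the floxed tumour of highest median. The fibroblast and hypoxia lists also failed without certain other samples. Skeletal muscle markers (median 0.29, 22 of 26 higher, adjusted p = 0.00323; Pgam2 at 0.51, Atp2a1 at 0.54, Mylpf at 0.77) had an adjusted p of 0.745 with an estimated correlation. Their median was 1.18 in floxed tumour 5, and without it the adjusted p was 0.181, with Atp2a1 at 0.35 and Mylpf at 0.37. Fibroblast and matrix genes (0.24, 28 of 44, 0.0403; Bgn at 1.14, Tnc at 1.13, Col5a2 at 0.78) had an adjusted p of 0.745 with an estimated correlation. Their median was 1.32 in floxed tumour 2, and without it the adjusted p was 0.986 and Tnc 0.66; without wild-type pool 3 Bgn was 0.67. Hypoxia-inducible and glycolytic genes (0.09, 27 of 41, 0.0111; Gpi1, Ero1a at 0.63, Higd1a at 0.79) likewise had an adjusted p of 0.745 with an estimated correlation. Their median was 0.64 in floxed tumour 5, with an adjusted p of 0.337 without it and 0.783 without wild-type pool 1, and Gpi1 passed adjusted over the list alone. Respiratory chain genes (0.14, 42 of 54, 9.11e-05) also had an adjusted p of 0.745 with an estimated correlation. They included Cox6a1 at 0.54, Atp5e at 0.51 and Ndufb7 at 0.36, which were 0.11, 0.12 and 0.13 in the tumour channel alone, where Gpi1 was 0.14 and Higd1a 0.42. With median centring in place of loess the respiratory chain (adjusted p = 0.102), hypoxia (0.110) and fibroblast (0.0639) lists did not pass. Fibroblast genes also did not pass with processed signals (0.111) or no filter (0.0515), nor dendritic markers with the filter on all 8 arrays (0.0677). Without wild-type pool 1, Higd1a was 0.45.

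**Figure D2:**
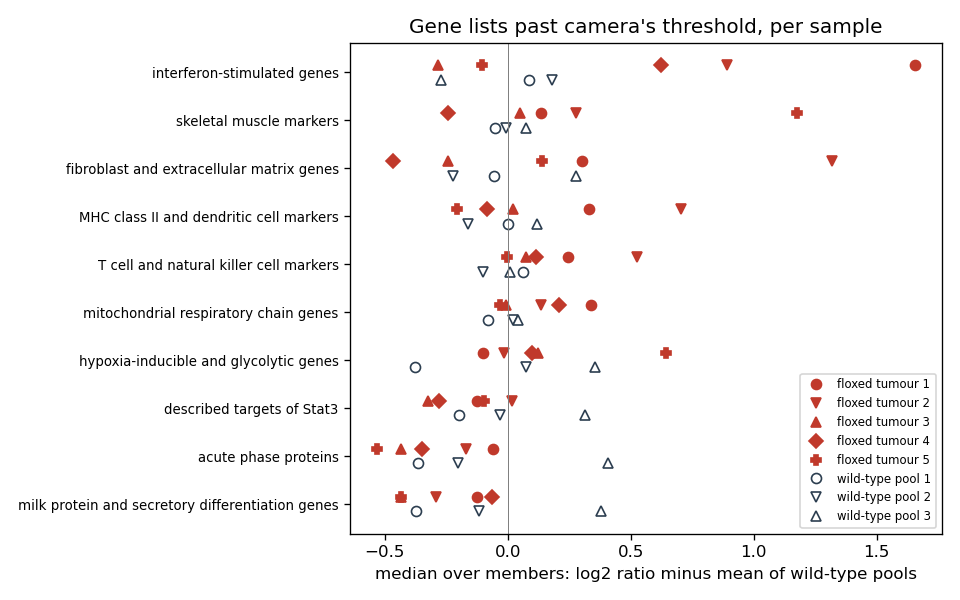
For the 10 lists past camera's preset threshold, the median over members of the log2 ratio minus the mean of the wild-type pools is plotted on the horizontal axis, with a filled marker for each floxed tumour and an open marker for each wild-type pool. Floxed tumour 1 reached 1.66 on interferon-stimulated genes, and wild-type pool 3 stood at 0.41 on acute phase genes.

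Within slides the direction held on all 3 for Stat3 targets (-0.40, -0.14 and -0.12 on the slides of pools 3, 2 and 1) and for interferon-stimulated genes (0.32, 1.35 and 0.29). It also held for skeletal muscle markers (0.11, 0.13 and 0.54) and respiratory chain genes (0.02, 0.32 and 0.13). It did not for acute phase genes (-0.81, 0.25 and -0.11), milk genes (-0.83, 0.16 and -0.00478), dendritic markers (0.18, 0.47 and -0.18), T and natural killer markers (0.25, 0.32 and -0.00446), fibroblast genes (0.30, 0.42 and -0.13) and hypoxia genes (-0.35, -0.04 and 0.71). With slide as a fixed block the medians were -0.16 for Stat3 targets, -0.27 for acute phase genes and -0.29 for milk genes. They were 0.58 for interferon-stimulated genes, 0.19 for T and natural killer markers and 0.24 for dendritic markers. For muscle, fibroblast, hypoxia and respiratory chain genes they were 0.28, 0.22, 0.07 and 0.16. The fibroblast (adjusted p = 0.114) and milk (0.0525) lists then no longer passed. Other samples left out also ended calls. Stat3 targets no longer passed without floxed tumour 4 (adjusted p = 0.0644) or wild-type pool 2 (0.135), nor milk genes without floxed tumour 2 (0.0984), floxed tumour 5 (0.0799), pool 2 (0.0760) or pool 3 (0.359). Dendritic markers no longer passed without floxed tumour 1 (0.0801), floxed tumour 2 (0.450) or pool 2 (0.306), nor fibroblast genes without floxed tumour 1 (0.0801), floxed tumour 5 (0.0799) or pool 2 (0.296). As many lists passed in 37 of the 56 splits of the samples, so the number of lists is no larger than regrouping the same samples gives.

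The remaining 23 lists did not pass. Camera's adjusted p was 0.0547 for pericyte and smooth muscle markers and for proteases, 0.0563 for ErbB signalling, 0.0687 for angiogenic factors, 0.0821 for macrophage, luminal and epidermal keratinocyte genes and 0.0857 for endothelial markers. It was 0.132 for immediate early genes, 0.166 for chaperones, 0.173 for complement, basal and proliferation genes and 0.230 for C/EBP, chemokine and epithelial to mesenchymal transition genes. It was 0.271 for neutrophil markers, 0.291 for B cell markers and apoptosis regulators, 0.422 for mast cell markers, 0.489 for the IL-6, JAK and STAT list, 0.769 for erythroid and 0.994 for adipocyte genes. Among immediate early genes, Fos differed by -0.79, Atf3 by 0.60 and Dusp1 by 0.45, and among C/EBP genes besides Cebpd, Cebpg by 0.12 and Cebpz by -0.17 (adjusted p from 0.942 to 0.967). Cebpz was 0.00315 without floxed tumour 1 and -0.39 without wild-type pool 3, and Cebpg 0.02 to 0.21 with 1 sample left out, so neither has a settled size and Cebpz no settled direction. Over all lists 0 genes passed adjusted over all genes and 10 distinct genes passed adjusted over the list alone, the others being Fas and Il12a, which like Osmr and Pik3r1 were named after their values were seen. Fry called 0 lists for a shift on balance and 3 for change in either direction. These were Stat3 targets (fry adjusted p = 0.0147), C/EBP genes (0.0147) and the IL-6, JAK and STAT list (0.0413). Each holds Stat3 or Cebpd, and none was tested without these genes.

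The median SD over genes was 0.279 between the 5 floxed tumours and 0.250 between the 3 wild-type pools. The SD was larger among floxed tumours for 56.3% of genes. Unequal group sizes alone shift both values in this direction, so more spread among floxed tumours is not shown.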

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

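Chosen only after the results were seen were the tests of splits, of the pick of a family and of the segment for the protocadherins, of immune cells and slide for the interferon genes, and of other tissue and myeloid cells for wild-type pool 3. A floxed tumour was listed where its distance to the nearest other exceeded Dixon's critical value, in 6 of 75 sets of values, where chance gives about 3.75. The log2 ratio of Dppa1 was 0.76 in floxed tumour 4 against -0.04 to 0.10 in the others, but the probe was not well above background in any of them, so these values carry no order. That of Atf3 was 0.72 in floxed tumour 2 against -0.19 to 0.04, that of Cebpz -1.36 in floxed tumour 1 against -0.62 to -0.40, and that of Wap 1.88 in floxed tumour 4 against 0.19 to 0.40. The immediate early list median was 0.28 in floxed tumour 5 against -0.01 to 0.04, and the epithelial to mesenchymal transition list median 0.36 in floxed tumour 2 against -0.07 to 0.05.

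Chance could not be excluded for the counts of the comparison. As many genes passed the threshold in 4 of 56 splits of the samples (1 gene in the real split, 80 in the highest other), and as many passed the second threshold in 17 of 56 (155 against 716). As many lists passed in 37 of 56 (10 against 23). The split with 80 genes set floxed tumour 1 with wild-type pools 1 and 3, several times the real count, which points to a structure of the samples that was not tested further; those 3 arrays lay on 3 different slides.

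Beta protocadherin genes, a cluster of cell adhesion genes on chromosome 18, were lower in floxed tumours: 14 of 20 measured members passed an unadjusted p of 0.05, all 14 lower, with Pcdhb4 at -1.64 and Pcdhb7 at -2.64. Taken alone the family median of -0.87, as the group of 5 minus the group of 3, was lowest in 1 of 56 splits (-0.75 in the next). Setting floxed tumours 2, 3 and 5 apart as the group of 3 gave a larger absolute median (0.90), the family being lower in those tumours. The family was picked because it stood out, and in 12 of 56 splits some family among 171 reached as large a median (up to 1.22), so chance stays open. Probes shared a median longest stretch of 9 of 60 bases (at most 23), under the bound set beforehand, but probes at different places of related transcripts share few bases either way, so cross-hybridization stays open. The 77 other genes within 2 Mb had a median of 0.0018 (standard error 0.0596), which argues against a shift of the whole segment.

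The interferon list was high in floxed tumours 1, 2 and 4, but a median difference as high (0.51) came in 9 of 56 splits (up to 0.89). That count took the group of 5 minus the group of 3, and the higher direction only. Setting floxed tumours 1, 2 and 4 apart as the group of 3 gave -1.17, the list being higher in those tumours. No link to genotype is thus shown. Macrophage, T and natural killer markers lay below the list by 1.33 in floxed tumour 1, 0.36 in tumour 2 and 0.51 in tumour 4. The standard errors over genes were 0.198, 0.162 and 0.152. The marker median was 0.33, 0.53 and 0.12 in tumours 1, 2 and 4, against -0.21 and 0.10 in tumours 3 and 5. The test takes markers and list to rise equally, which is not known, so it cannot exclude more immune cells as a cause. Floxed tumours sharing a slide differed by 1.17 and 0.727, which argues against slide. Genes of a list vary together, so these standard errors are too small; an interferon response differing between single tumours may be the source and was not tested.

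Wild-type pool 3 exceeded pools 1 and 2 on acute phase genes by 0.61 (standard error 0.262). The tumour channel alone gave 0.428 (standard error 0.232), too uncertain to settle whether the reference channel took part. Adipocyte (-0.33) and muscle (0.109) markers argue against those tissues. Neutrophil (0.43, standard error 0.288) and macrophage (0.376) markers were also higher, as more myeloid cells would give, but both lie within 2 standard errors of the bound, macrophage markers also differed between pools 1 (0.02) and 2 (-0.31), and luminal (0.58), basal (0.79) and endothelial (0.55) genes were as high, so this may not be specific. Apart from slide, the labels give no group that sets pool 3 apart. Each pool lay on its own slide, so a difference between pools cannot be told apart from slide by the pools alone. Floxed tumours 2 and 3, on the slide of pool 3, had acute phase medians of -0.17 and -0.43.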

How the results depend on the processing

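No paired analysis was possible because the replicate numbers of the floxed tumours are only accession order and pair no samples; slide, which holds both groups, was used as a block instead. The count of 1 gene (Dppa1) stayed within 1.5 times under median centring, the mean of probes, flagged spots kept, slide as a random block and array weights. Between-array normalization leaves ratios unchanged, so it tests nothing here. The count was 0 without background subtraction, with processed signals, with the tumour channel only and with no filter. The same held for the filter on all 8 arrays, the authors' table, slide as a fixed block and trended robust variances. The filter on all 8 arrays removes Dppa1 before testing, so Dppa1 could not be called there. At the second threshold the count was 155. Leaving out 1 sample gave 0 to 2: Htr5b with Dppa1 without floxed tumour 4, Stat3 without wild-type pool 1, the clone 2410076I21Rik without pool 2, and 0 without floxed tumours 1, 2, 3 or 5 or without pool 3. Dppa1 and Stat3 were lower wherever tested. Stat3 differed by -1.32 to -2.34 over the alternatives on all samples, -1.32 being the mean of both probes (adjusted p = 0.702), and by -2.36 to -1.79 with 1 sample left out, passing only without wild-type pool 1 (adjusted p = 0.028, range over alternatives 0.028 to 0.702). Within slides it was -2.68 (slide of pool 3) and -1.29 (slide of pool 1). The 10 lists became 18 with the mean of all probes, 0 with an estimated correlation, 0 with fry and 7 to 19 with 1 sample left out (19 without floxed tumour 3, 16 without wild-type pool 3). Within slides, medians turned for hypoxia genes (-0.35 and -0.0402), acute phase (0.25), milk (0.16), dendritic (-0.18), T and natural killer (-0.00446) and fibroblast genes (-0.13). Interferon and T and natural killer lists passed in all 21 other tested alternatives at the preset correlation, Stat3 targets in 19 of 21 and acute phase in 20 of 21. All of these alternatives share the preset of 0.01, so they do not test it. The estimated correlations were 0.645 for the interferon list, 0.259 for T and natural killer markers, 0.135 for Stat3 targets and 0.306 for acute phase genes. The median SD with 1 sample left out was 0.230 to 0.287 among floxed tumours (lowest without tumour 1) and 0.168 to 0.223 among wild-type pools (lowest without pool 3). Apart from what the construction shows, such as fewer samples, the cause was not tested. Within-slide gene counts were not computed, since a slide holds 1 wild-type pool. Signal over background limits Dppa1 and Ocm, which were not well above background in any floxed tumour.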

Other observations

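The neighbourhood of the floxed allele was examined with a test written before its result was seen. Of 403 genes within 10 Mb of Stat3 on chromosome 11, 24 (5.96%) passed an unadjusted p of 0.05, against 1019 of 20750 elsewhere (4.91%). A linked chromosome segment carried along with the floxed allele may raise that share, but Fisher's exact test, one-sided, gave p = 0.197, which leaves the hypothesis open.

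The wild-type pools also differed among themselves on lists besides acute phase genes. Relative to their mean, the medians of pools 1, 2 and 3 were 0.30, -0.00755 and -0.25 for proliferation genes and -0.38, 0.08 and 0.36 for hypoxia genes. For interferon-stimulated genes they were 0.09, 0.18 and -0.27. On the first 2 principal components, which held 26.1% and 25.1% of the variance, pool 3 lay at -57.0 and -44.5 and floxed tumour 1 at -18.4 and 63.3.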
